A study of Danio rerio with 20 samples.

How the data were processed

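RNA sequencing libraries were made from whole zebrafish (Danio rerio) larvae that were 10 days post-fertilization when sampled. The larvae had been exposed for 48 hours to lithium cobalt oxide (LCO) nanosheets at 1 or 10 mg/L, to a treatment that the labels call ion without giving its makeup or dose, or to neither (control). Each of the 20 libraries came from a pool of 20 larvae, and the 4 groups held 5 libraries each. Per the series' design text, 6 replicates were collected per treatment and samples were chosen on RNA quality. The replicate numbers run to 6 with gaps, which that choice may explain.

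The authors deposited 1 table per library with the length, effective length, estimated count and TPM of the same 57775 Ensembl transcripts. Per the submitters' processing notes, the tools were FastQC 0.11.5, cutadapt 1.18 and kallisto 0.45.0, with genome build GRCz11. The notes give no settings. The column names are those of kallisto, which assigns reads to transcripts by pseudoalignment and shares a read among the transcripts it fits. The deposited estimated counts are therefore expected counts, and between 58.1% and 64.3% of the values in a library were not whole. The deposited TPM values equalled those recomputed from the estimated counts and effective lengths to within 0.00105%, over values above 1, and they were not used in any test. The deposited effective length is the transcript length less a gap that depends on the fragment lengths of the library, and that gap was read from transcripts longer than 3000 bases.

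Total estimated counts ranged from 24950500 to 63120000 per library. None of the 57775 transcript identifiers matched the gene name tables used here (0 matches). The tests were therefore run per transcript, and no gene symbol is given. The 40 gene lists fixed before the data were examined, the indicator genes of the naming rule and a fit on protein coding genes only could not be run for the same reason. A transcript can change because its gene changed or because reads moved between transcripts of 1 gene, and the 2 cannot be separated here.

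Estimated counts were rounded and tested in R 4.3.3 with edgeR 4.0.16. Transcripts were kept by filterByExpr at its defaults with the groups (minimum count 10), which left 39355 transcripts, and the lowest share of counts kept in a library was 99.9% after rounding. Libraries were scaled by TMM. One fit held all 20 libraries with group as the single factor, and each comparison was a contrast in that fit, tested two-sided by glmQLFTest. A transcript was called at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Abundances are CPM on the TMM scale, given as mean ± SD. The fit and the 5 comparisons were fixed before the data were examined, and the comparison of LCO 1 mg/L with ion was added afterwards. Because the labels do not say whether pools of larvae shared parents or tanks, p-values measure the spread between these pools.

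The naming rule fixed beforehand took the largest rises and falls among called transcripts with a mean log2 CPM of at least 1 and an informative gene symbol. With no symbols, it was applied without that condition to 2 transcripts per direction and comparison, and transcripts with identical counts were taken once. That change was made after the files had been seen. Among the kept transcripts, 208 repeated the rounded counts of another, so reads could not be told apart between them. Where every library of a group was at 0, the fold is a lower bound against a floor of 3 counts over the group. Intervals and floors of this kind cover counting error only.

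Replicates were compared before averaging. No 2 libraries were identical (0 pairs), and the 40 pairs within groups had a chi-square per degree of freedom of at least 12.0, so no library was counted as a repeat of another. Library measures were compared by exact two-sided permutation tests, adjusted over a family of 12. Correlations of fold changes were set beside 20 simulations of unchanged groups against the same controls and beside 20 pairings of disjoint sets of controls. For these correlations, fold changes were differences of group means of log2 CPM with a prior count of 2.

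The test was checked on counts simulated from the means, library sizes and dispersions of the 39355 transcripts. The changed transcripts were drawn only from those above a minimum mean CPM, and far fewer were changed than were called in the data. The shares recovered therefore do not hold for transcripts of low abundance or for all those tested. For LCO 10 mg/L vs control, 33 of 67 transcripts changed by 1.5-fold were recovered, 45 of 67 changed by 2-fold and 63 of 66 changed by 4-fold, and 7 of the 148 calls were false. With no change simulated, 0 transcripts were called in each of the 5 comparisons. Each transcript was drawn on its own, so the simulated libraries held no variation shared between transcripts. They therefore cannot show how many false calls such variation would give. The unchanged groups simulated for the correlations were drawn in the same way.

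The alternatives fixed beforehand were RLE scaling, DESeq2 1.42.0, limma-voom with quality weights (limma 3.58.1), no filter, a CPM above 1 in at least 5 libraries, an effective length offset, fits of the compared groups alone, a replicate block and leaving out each library. Alternatives chosen after seeing the data were the fragment length gap as a covariate, thinning to equal totals, collapsing identical transcripts, using the same 2 or 3 controls in both comparisons of a correlation, leaving out LCO 10 mg/L replicates 2 and 3, and leaving out the 8 libraries that stood apart on the first principal component. A fit with the side of that component as a term was also run and was set aside, because the sides were read from the expression values that the fit tests. Each comparison was also refitted on 100 of the 126 splits of its 10 libraries into 5 and 5, the real one included.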

Results

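Transcript abundance was measured by RNA sequencing in whole zebrafish larvae exposed for 48 hours to nanosheets of lithium cobalt oxide (LCO), a cathode material of lithium-ion batteries, or to an ion treatment. There were 5 libraries each for control, LCO 1 mg/L, LCO 10 mg/L and ion, each from a pool of 20 larvae. Library totals ranged from 32568900 to 63120000 estimated counts in controls, 30439900 to 52060300 at 1 mg/L, 24950500 to 47031900 at 10 mg/L and 35012700 to 49469200 under ion. The files do not pair transcript identifiers with genes, so transcripts are given by identifier, without gene names.

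The first principal component of log2 CPM held 14.7% of the variance and parted libraries within each exposed group. All 5 controls, LCO 10 mg/L replicate 1, ion replicates 1, 2 and 3 and LCO 1 mg/L replicates 3, 5 and 6 had scores of -20.8 or lower. The other 8 libraries, 4 of LCO 10 mg/L and 2 each of LCO 1 mg/L and ion, had scores of 20.9 or higher. No control lay on that side (0 of 5). The labels give no batch to which this separation could be matched. On the second component the controls did not overlap with the LCO libraries. All 5 controls had scores of 23.1 or higher there, and every LCO library, at either dose, had a score of 6.46 or lower. The ion libraries ranged from -3.74 to 72.9 and so lay on both sides. The cause of that second separation was not tested.

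**Figure D1:**
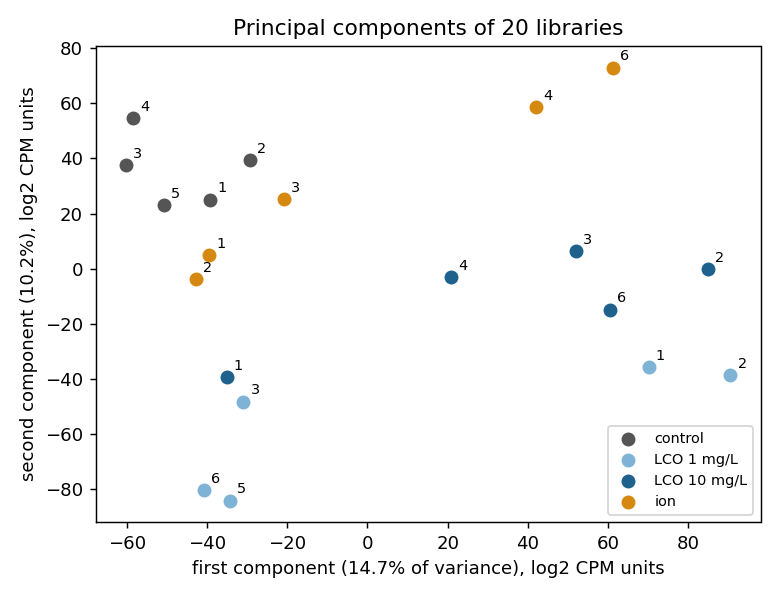
Scores of the 20 libraries on the first 2 principal components of log2 CPM, coloured by group and numbered by replicate. The first component (14.7% of variance) parts 12 libraries, all 5 controls among them, from 8 exposed libraries. On the second component every control has a higher score than every LCO library.

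The comparison of LCO 1 mg/L with control asked which transcripts differed after exposure to the lower dose. Among called transcripts with a mean log2 CPM of at least 1, the largest falls were in ENSDART00000169128.2 and ENSDART00000181371.1. ENSDART00000169128.2 was at 245 ± 79.5 CPM in controls and at 0 in all 5 libraries of 1 mg/L (SD, n = 5), at least 16282-fold lower, with an adjusted p of 1.98e-05 by edgeR. ENSDART00000181371.1 was at 53.1 ± 20.3 CPM in controls and also at 0 in all 5 libraries, at least 3524-fold lower (edgeR adjusted p = 0.000611). Within the same abundance limit the largest rises were in ENSDART00000181955.1, from 0.417 ± 0.586 to 14.0 ± 18.1 CPM, and ENSDART00000141549.2, from 1.45 ± 1.05 to 22.8 ± 29.8 CPM, with edgeR adjusted p of 0.0199 and 0.0191. Both rises were carried by replicates 5 and 6, at 41.6 and 23.4 CPM for the former and 44.3 and 64.6 CPM for the latter. The former lost its call without control replicate 3, control replicate 5 or LCO 1 mg/L replicate 5, and the latter without LCO 1 mg/L replicate 6 (edgeR adjusted p up to 0.0771 and 0.0598). The log2 fold change of the former, 5.12, was 4.13 without replicate 5 and 6.34 without control replicate 4, and that of the latter, 3.93, was 3.07 without replicate 6. In settings chosen after seeing the data they were 8.34 and 4.72 with the fragment length gap as a covariate and 5.86 and 4.63 without the 8 libraries apart on the first component, and both kept their calls. The falls kept their calls without any 1 library, at an edgeR adjusted p of at most 8.88e-05 and 0.00194, but limma-voom called neither (adjusted p = 0.752 and 0.479) nor either rise (0.460 and 0.240).

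In all, 5016 of 39355 transcripts were called at 1 mg/L, 1708 higher and 3308 lower. The median fold of the rises was 1.22 and that of the falls 1.70. Of the calls, 1173 were at least 2-fold, 36 of them rises and 1137 falls. Over all 39355 transcripts, the 5 exposed libraries lay above the 5 controls in 1226 and below them in 2760, where chance gives 156 in each direction (0.794% in both together). Called rises were in longer transcripts than called falls, with median lengths of 3288 and 1844.5 bases against 1857 bases for all tested. The same held at 10 mg/L, at 3294.5 and 1777 bases. Over all tested transcripts, the median log2 fold change rose from the shortest to the longest quartile of length in each exposed group. It went from -0.057 to 0.075 at 1 mg/L, from -0.076 to 0.066 at 10 mg/L and from -0.046 to 0.052 under ion. It also rose with abundance, from -0.118 in the lowest tercile to 0.065 in the highest at 1 mg/L and from -0.090 to 0.030 at 10 mg/L. Under ion it went from -0.015 to -0.0002. The highest tercile held 1444 of the 1708 rises at 1 mg/L and 1457 of the 3308 falls. Length and abundance were not separated. These comparisons share the controls, and the cause was not tested. The count of calls at 1 mg/L was 3297 without the 8 libraries apart on the first component and 2649 with the fragment length gap as a covariate, both chosen after seeing the data.

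At 10 mg/L the largest falls with a mean log2 CPM of at least 1 were in ENSDART00000074463.6 and ENSDART00000191756.1. ENSDART00000074463.6 went from 12.3 ± 13.4 CPM in controls to 0 in all 5 libraries, at least 636-fold lower (edgeR adjusted p = 0.0405). ENSDART00000191756.1 went from 5.89 ± 3.69 CPM to 0 in all 5, at least 304-fold lower (edgeR adjusted p = 0.0102). The former lost its call without each library except control replicate 5 (edgeR adjusted p up to 0.0804), and the latter kept it in all 10 cases (at most 0.0268). Both lost their calls with the fragment length gap as a covariate (edgeR adjusted p = 0.140 and 0.0830). They also lost them without LCO 10 mg/L replicates 2 and 3 together (edgeR adjusted p = 0.163 and 0.0591). ENSDART00000074463.6 was also at 0 in all 5 libraries of 1 mg/L and in 2 of 5 under ion. The largest rises within that limit, in ENSDART00000180809.1 (8.80 ± 6.18 to 392 ± 686 CPM) and ENSDART00000185964.1 (74.1 ± 61.4 to 1180 ± 1622 CPM), were carried by replicates 2 and 3. These held 350 and 1589 CPM of the former, which shares its counts with 1 other identifier, and at most 8.08 CPM was seen in the other 3 libraries. Their edgeR adjusted p were 0.0157 and 0.0245. The log2 fold changes, 5.49 and 3.99, were -0.40 and -0.30 without both replicates, and neither was then called. That of the former was 3.40 without replicate 3, and that of the latter 2.95 without replicate 2, 4.66 without control replicate 4 and 2.88 with the fragment length gap as a covariate, which ended both calls (edgeR adjusted p = 0.256 and 0.503). The former also lost its call without replicate 3 alone (edgeR adjusted p = 0.0594), and the latter without replicate 2, replicate 3 or control replicates 1, 2, 3 or 5 (up to 0.0850). With limma-voom the adjusted p of the 2 falls were 0.583 and 0.376 and those of the 2 rises 0.197 and 0.0950.

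The edgeR test called 2470 transcripts at 10 mg/L, 898 higher and 1572 lower, with median folds of 1.26 and 1.55. Of these, 309 were at least 2-fold, 49 rises and 260 falls. Over all 39355 transcripts, the exposed libraries lay above the controls in 1275 and below them in 1980, where chance gives 156 in each direction. The count fell to 1215 without control replicate 3, 1212 without control replicate 4, 1296 without LCO 10 mg/L replicate 2, 1557 without replicate 3 and 1356 without replicate 6, and to 567 without replicates 2 and 3 together. It was 207 with the fragment length gap as a covariate and 33 without the 8 libraries apart on the first component, which left 1 library of 10 mg/L, assumed to vary like the other groups.

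Of the 898 rises at 10 mg/L and the 1708 at 1 mg/L, 605 were called at both doses, where independent lists would share 39.0. Of the 1572 falls at 10 mg/L and the 3308 at 1 mg/L, 1376 were called at both, where independent lists would share 132. No transcript was called in opposite directions (0). With the controls divided so that the doses shared none, the medians over 20 divisions were 71.5 shared rises and 368 shared falls, where independent lists would share 2.23 and 23.4. Across transcripts, which are not independent replicates, the log2 fold changes at 10 and 1 mg/L had r = 0.67. Unchanged groups simulated against the same controls gave 0.49. Their covariance was 0.220, against 0.0801 simulated. With disjoint controls the observed r was 0.35 (0.309 to 0.380 over 20 pairings) and the observed covariance 0.143 (0.129 to 0.154). Those are observed values from fewer controls, not values expected without an effect. The standard error of the r of 0.67, from leaving out each library in turn, was 0.11, and its excess over the simulated value was 0.17.

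**Figure D2:**
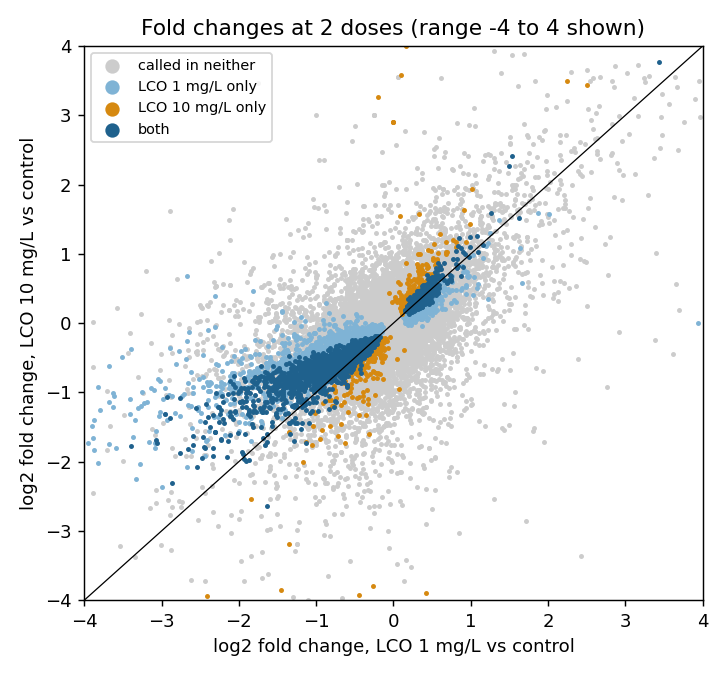
Log2 fold change against control of each transcript at 1 mg/L (horizontal) and 10 mg/L (vertical), coloured by where it was called, with the line of equal change. Both comparisons share the 5 controls, and transcripts beyond 4 on either axis (275 of 39355) are not drawn. Transcripts called at both doses lie in the lower left and upper right, and none was called in opposite directions (0).

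Directly compared, 84 transcripts differed between the doses by edgeR, and 83 of them were higher at 10 than at 1 mg/L. Without the 8 libraries apart on the first component, a setting chosen after seeing the data that left 1 library of 10 mg/L, 1 was higher and 6 were lower at 10 mg/L. Of the 83, 80 were called as falls at 1 mg/L against control and 47 as falls at 10 mg/L. The comparison between the doses shares its 5 libraries of 1 mg/L with the former and those of 10 mg/L with the latter, which by itself shifts these overlaps, and no simulated value without effect was made for them. ENSDART00000169128.2 was at 34.9 ± 21.6 CPM at 10 mg/L, its group mean at least 2315-fold higher than at 1 mg/L (edgeR adjusted p = 0.0158). In LCO 10 mg/L replicate 4 it was at 0, as in all 5 libraries of 1 mg/L, so that fold does not hold for each library. Besides ENSDART00000169128.2, the largest with a mean log2 CPM of at least 1 was ENSDART00000164665.2. It was at 34.2 ± 5.42 CPM in controls, 34.1 ± 17.3 under ion, 17.1 ± 6.11 at 10 mg/L and 3.63 ± 3.38 at 1 mg/L, 4.79-fold higher at 10 than at 1 mg/L (edgeR adjusted p = 0.0475). The 1 transcript lower at 10 mg/L was ENSDART00000190477.1, at 5.90 ± 1.01 against 8.84 ± 1.07 CPM (edgeR adjusted p = 0.0475). ENSDART00000169128.2 lost its call without LCO 10 mg/L replicate 3 or LCO 1 mg/L replicate 6 (edgeR adjusted p up to 0.0574). ENSDART00000164665.2 kept it only without LCO 10 mg/L replicate 6 or LCO 1 mg/L replicate 3 and ENSDART00000190477.1 only without LCO 10 mg/L replicate 1 or LCO 1 mg/L replicate 3 (up to 0.151 and 0.153). Without LCO 1 mg/L replicate 3, which held 9.63 CPM of ENSDART00000164665.2, its log2 fold change was larger by 0.74 than with all libraries (2.26). With limma-voom none of the 3 was called, at adjusted p of 0.893, 0.178 and 0.0859 in that order. The count of 84 became 7, 2 and 2 without LCO 10 mg/L replicates 2, 3 and 4, 159 without replicate 6, and 15, 11, 226, 21 and 1 without LCO 1 mg/L replicates 1, 2, 3, 5 and 6. It was 0 when only these 2 groups were fitted, with 2505 transcripts at an unadjusted p under 0.05, while DESeq2 called 442 and limma-voom 8.

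Under ion, 3 transcripts were higher than in controls and 11 lower by edgeR. ENSDART00000110490.4 rose 8.33-fold, from 2.45 ± 0.880 to 20.3 ± 12.2 CPM (edgeR adjusted p = 0.0142), and ENSDART00000109791.4 also 8.33-fold, from 0.686 ± 0.145 to 5.75 ± 3.73 CPM (edgeR adjusted p = 0.0184). Both were also called as rises under LCO. ENSDART00000110490.4 was 5.32-fold higher at 10 mg/L and 2.89-fold higher at 1 mg/L, and ENSDART00000109791.4 was 4.83-fold and 2.82-fold higher, with edgeR adjusted p from 0.00351 to 0.0386. Against ion, both were lower at 1 mg/L (edgeR adjusted p = 0.0260 and 0.0374), while at 10 mg/L the difference did not pass (0.587 and 0.531). The falls included ENSDART00000193557.1, from 9.63 ± 2.02 to 4.47 ± 0.71 CPM, and ENSDART00000158624.2, from 3.95 ± 0.904 to 1.88 ± 0.200 CPM, with edgeR adjusted p of 0.0142 and 0.0184. Both were also called as falls at 1 and 10 mg/L. Calls under ion were lost without control replicate 5 or ion replicate 3 for ENSDART00000110490.4, without ion replicate 2 or 3 for ENSDART00000193557.1, and without control replicates 2, 3, 4 or 5 or ion replicates 2, 3 or 6 for ENSDART00000109791.4 and ENSDART00000158624.2, with edgeR adjusted p up to 0.0842.

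**Figure D3:**
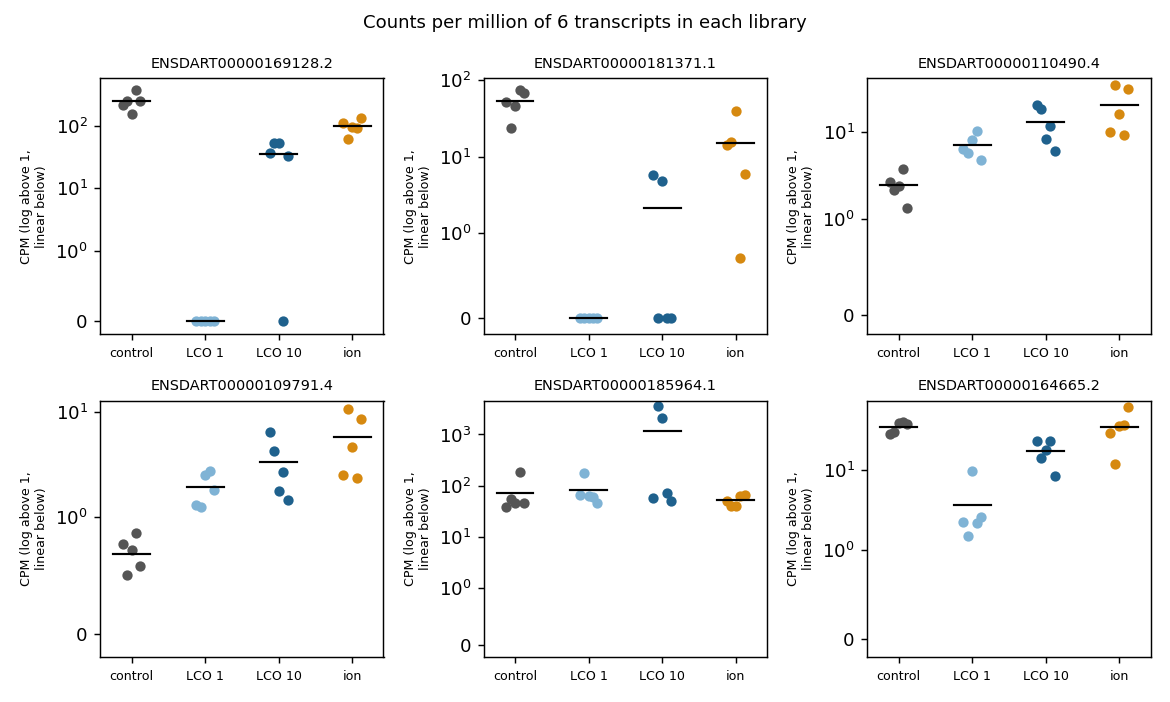
CPM of 6 transcripts in each library, by group (LCO 1 and LCO 10 in mg/L), with points for libraries and bars for group means, on an axis that is logarithmic above 1 and linear below. ENSDART00000169128.2 was at 0 in all 5 libraries of LCO 1 mg/L, and the high mean of ENSDART00000185964.1 at 10 mg/L came from replicates 2 and 3.

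Of the 14 transcripts called under ion, 3 of 3 rises and 10 of 11 falls were also called in the same direction at 10 mg/L, where independent lists would share 0.0685 and 0.439. Both comparisons use the same 5 controls, which add to this overlap, and with the controls divided the median count under ion was 0, so the overlap could not be measured without them. The count became 6, 6, 4 and 2 without control replicates 2, 3, 4 and 5, and 3, 0 and 5 without ion replicates 2, 3 and 6. Without ion replicate 3, 3766 transcripts had an unadjusted p under 0.05. With only these 2 groups fitted edgeR called 0, with 5197 at an unadjusted p under 0.05, while DESeq2 called 311 and limma-voom 76. Log2 fold changes under ion and at 10 mg/L had r = 0.59 across transcripts, against 0.49 simulated, and a covariance of 0.152, against 0.0798. With disjoint controls the observed r was 0.22 (0.156 to 0.251 over 20 pairings) and the observed covariance 0.0757 (0.0558 to 0.0870). Those are observed values from fewer controls, not values expected without an effect. The standard error of the r of 0.59, from leaving out each library in turn, was 0.11. The excess of r over the simulated value, 0.10, was smaller than this error.

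LCO 10 mg/L and ion differed in 67 transcripts by edgeR, 48 higher and 19 lower at 10 mg/L. ENSDART00000111038.4 was 2.88-fold higher, at 4.78 ± 1.12 against 1.66 ± 0.369 CPM, and ENSDART00000148809.3 was 2.82-fold higher, at 22.5 ± 6.84 against 7.99 ± 2.52 CPM, with edgeR adjusted p of 0.00312 and 0.0336. Controls lay between, at 2.55 ± 0.276 and 14.9 ± 3.85 CPM. ENSDART00000130970.3 was 2.62-fold lower, at 2.20 ± 0.407 against 5.75 ± 1.77 CPM, and ENSDART00000145432.2 was 2.57-fold lower, at 3.77 ± 1.26 against 9.73 ± 2.80 CPM, with edgeR adjusted p of 0.0409 and 0.0465. ENSDART00000111038.4 kept its call without any 1 library (edgeR adjusted p at most 0.0155). ENSDART00000148809.3 lost it without LCO 10 mg/L replicates 3, 4 or 6 or ion replicates 3, 4 or 6, ENSDART00000130970.3 without each library except ion replicate 2, and ENSDART00000145432.2 without each except ion replicate 6 (edgeR adjusted p up to 0.106, 0.107 and 0.120). The count became 40, 19, 23 and 32 without LCO 10 mg/L replicates 2, 3, 4 and 6, and 30, 19, 20 and 24 without ion replicates 1, 3, 4 and 6. Without the 8 libraries apart on the first component it was 8, 0 higher and 8 lower, and the log2 fold change of ENSDART00000111038.4 was 0.90 instead of 1.53 (edgeR adjusted p = 0.786). LCO 1 mg/L and ion, compared after seeing the data, differed in 2380 transcripts, 629 higher and 1751 lower at 1 mg/L. That count was 3828 with DESeq2, 1188 with only these 2 groups fitted, 1546 without ion replicate 4 and 389 without the 8 libraries apart on the first component.

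**Figure D4:**
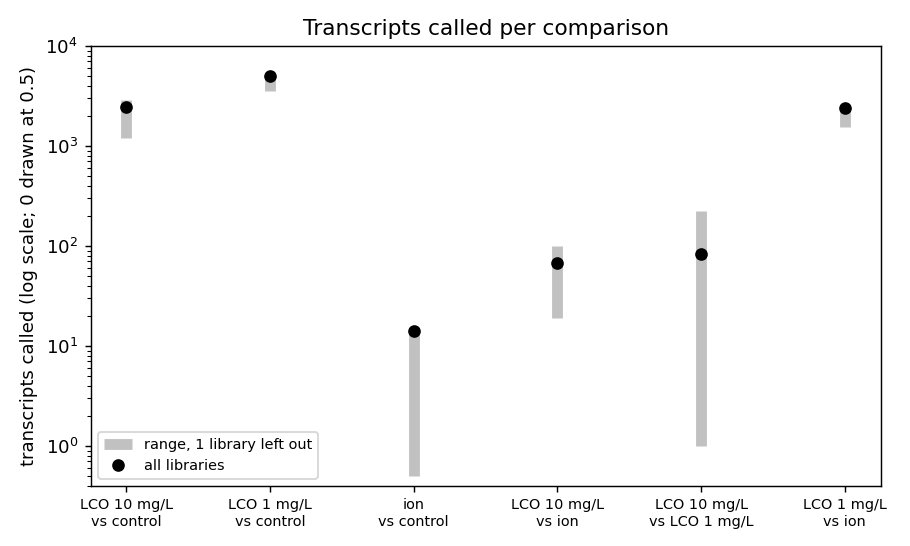
Transcripts called by edgeR in each comparison with all libraries (points) and the range when each library of the compared groups was left out in turn (bars), on a log axis with 0 drawn at 0.5. The points lie at 2470, 5016, 14, 67, 84 and 2380.

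Measures of whole libraries were also compared with controls. The gap between length and effective length was 152 ± 5.98 bases in controls, 161 ± 4.39 at 1 mg/L, 162 ± 3.60 at 10 mg/L and 158 ± 6.06 under ion. Its exact permutation p against control was 0.0635, 0.0397 and 0.167 in that order, and 0.152, 0.143 and 0.286 after adjustment over 12 tests. Transcripts detected after thinning each library to the same total count numbered 43950 ± 409 in controls, 43236 ± 260 at 1 mg/L, 43088 ± 467 at 10 mg/L and 43878 ± 276 under ion, with exact permutation p of 0.0238, 0.0238 and 0.722, and 0.143, 0.143 and 0.788 after adjustment. The 50 most abundant transcripts held 19.7 ± 0.351% of the counts in controls, 20.0 ± 0.812% at 1 mg/L, 21.9 ± 2.58% at 10 mg/L and 19.7 ± 0.913% under ion, with exact permutation p of 0.603, 0.0476 and 0.952, and 0.724, 0.143 and 0.952 after adjustment. None of the 12 differences passed after adjustment (0 of 12), and 0.00794 was the smallest p that 5 against 5 libraries can give. A lone difference, however clear, could therefore not pass over 12 tests. The result does not show that the groups were alike in these measures.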

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

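The tests of fragment length, of depth by thinning, of the libraries apart on the first component and of an outside source of RNA and the comparison of LCO 1 mg/L with ion, splits included, were chosen after the data had been seen, although the limits for depth and splits were set before the thinned and split counts were seen.

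In 6 of 54 groups of 5 libraries tested for a value far from the rest, 1 library stood apart (gap over range above 0.71), and chance gives about 5% of groups. In LCO 1 mg/L, replicate 1 had 21.4% of its counts in its 50 most abundant transcripts, against 19.3% to 19.8% in the others (0.758). Control replicate 4 stood apart for ENSDART00000180809.1, at 19.5 CPM against 4.80 to 8.78 (0.729), for ENSDART00000185964.1, at 183 CPM against 38.3 to 55.9 (0.879), and for ENSDART00000193557.1, at 13.1 CPM against 8.0 to 9.47 (0.712). LCO 10 mg/L replicate 3 held 1589 CPM of ENSDART00000180809.1 against at most 350 CPM in the others (0.782). LCO 1 mg/L replicate 3 held 9.63 CPM of ENSDART00000164665.2 against 1.51 to 2.59 (0.866).

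More transcripts were called against control for LCO (5016 and 2470) than for ion (14), and after thinning all libraries to equal totals 4537 were called at 1 mg/L and 2244 at 10 mg/L, which argues against differences in total counts. With the fragment length gap as a covariate, the log2 fold changes of the called transcripts kept a median of 0.923 of their size at 1 mg/L and 0.836 at 10 mg/L. The calls fell to 2649 and 207. The mean gap was 152 bases in controls and 161 and 162 bases at 1 and 10 mg/L, so it differed along with the exposure. This setting therefore cannot decide whether fragment length was the cause. The median size of the log2 fold change went from 0.53 to 0.47 at 1 mg/L and from 0.51 to 0.43 at 10 mg/L, while the median SE went from 0.12 to 0.14 and from 0.12 to 0.14. The part of the smaller size and of the wider error in the lost calls was not separated. Without the 8 libraries apart on the first component, 3297 were called at 1 mg/L, 2513 of them among the 5016 called with all libraries. Those 8 libraries were picked from the same expression values, so that count is not an independent test of their part. At 10 mg/L the setting left 1 exposed library, and the log2 fold changes of the called transcripts kept a median of 0.836 of their size. The part of the 8 libraries there cannot be told apart from the exposure. Whether the pools of larvae differed in parents or tanks is open and untested, so an effect of LCO remains a hypothesis.

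Other splits of the same libraries bear on each count. For LCO 10 mg/L, LCO 1 mg/L and ion against control and for LCO 10 mg/L against ion, 1 of 100 splits, the real one, gave as many calls as observed (2470, 5016, 14 and 67). The highest of the others gave 1, 822, 1 and 4, which argues against chance in each, among the splits run. For the 2 doses, 2 of 100 splits gave at least 84, and the highest other gave 177, after exchanging LCO 10 mg/L replicate 6 with LCO 1 mg/L replicate 3. For LCO 1 mg/L against ion, 2 of 100 gave at least 2380, and the highest other gave 3531. That split set ion replicates 1 and 2 and LCO 1 mg/L replicates 3, 5 and 6 against the rest, close to the separation on the first component. In both, the share of splits with as many calls was under the limit set before the splits were counted. The highest other split in each still gave more calls than the real one, so these counts cannot exclude chance. The libraries have a structure besides the treatments.

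In LCO 10 mg/L replicates 2 and 3, 5 transcripts with a mean log2 CPM of at least 1 were at least 4-fold above the median library while replicates 1, 4 and 6 were at most 2-fold above it. Transcripts with identical counts were taken once, so ENSDART00000180809.1 is counted through the other identifier that shares its counts. The 5 transcripts held 7.21% and 1.26% of the counts of these libraries and at most 0.493% elsewhere, in control replicate 4, and 4 of the 5 were called at 10 mg/L. A single outside source of RNA would raise all of them in 1 ratio between the libraries, but 3 of the 5 ratios lay over 2-fold from their median of 3.79, with a range from 0.217 to 12.7. That argues against 1 source of fixed makeup, and several sources remain open. No biological explanation was tested.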

How the results depend on the processing

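Alternatives with thinning, the fragment length gap, identical transcripts collapsed, several libraries left out or part of the controls in both comparisons were chosen after seeing the data, and unless stated the cause was not tested. Calls for LCO 10 mg/L vs control (2470) became 4030 with DESeq2, 4377 with limma-voom, 207 with the gap as a covariate, 567 without LCO 10 mg/L replicates 2 and 3 and 33 without the 8 libraries apart on the first component. For LCO 1 mg/L vs control (5016) they became 2649 with the gap and 3297 without those 8. For ion vs control (14) they became 311 with DESeq2, 76 with limma-voom, 22 with a CPM above 1 in at least 5 libraries, 0 with the 2 groups alone (5197 at an unadjusted p under 0.05), 4 with the gap and 3 without those 8. For LCO 10 mg/L vs ion (67) they became 106 with RLE, 741 with DESeq2, 156 with limma-voom, 32 with no filter, 105 with a CPM above 1 in at least 5 libraries, 37 with the gap, 13 without LCO 10 mg/L replicates 2 and 3 and 8 without those 8. For LCO 10 vs 1 mg/L (84) they became 442 with DESeq2, 8 with limma-voom, 45 with no filter, 0 with the 2 groups alone (2505 unadjusted), 3 without LCO 10 mg/L replicates 2 and 3 and 7 without those 8. For LCO 1 mg/L vs ion (2380) they became 3828 with DESeq2, 1188 with the 2 groups alone and 389 without those 8. Leaving out libraries gave fewer samples, which by itself lowers counts.

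Leaving out 1 library at a time gave 1212 to 2881 calls for LCO 10 mg/L vs control, 3554 to 5367 for LCO 1 mg/L vs control, 0 to 15 for ion vs control, 19 to 100 for LCO 10 mg/L vs ion, 1 to 226 for the 2 doses and 1546 to 2502 for LCO 1 mg/L vs ion. The correlation of fold changes at 10 mg/L with ion (0.59) ranged from 0.54 to 0.63, and that of the 2 doses (0.67) from 0.60 to 0.69. Over the 14112 transcripts with a mean log2 CPM of at least 3 they were 0.76 and 0.79, against 0.49 and 0.50 simulated with unchanged groups and the same controls. Over all transcripts they were 0.22 and 0.35 with the controls divided into 2 and 3 between the comparisons, and 0.69 and 0.73 with the same 2 or 3 controls in both.

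Replicate numbers did not pair the libraries. The 25 same-numbered pairs had a mean correlation of -0.00792 after removing group means, 3 of them over 0.1, against 0.00164 for the other 125, and 4 of 20 libraries correlated best with their own number. With a replicate block the calls were 1793, 4000, 6, 67 and 21 in the order above and 1494 for LCO 1 mg/L vs ion (2380), and 12 of the 19 results on named transcripts lost their call (edgeR adjusted p from 0.0554 to 0.162).

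For the 19 results on named transcripts, 427 alternatives were run, of which 277 kept the call and direction, 146 kept the direction without the call and 4 turned it. Besides the 12 above, calls ended in 11 with limma-voom, 11 of 18 with the 2 groups alone, 4 with no filter, 8 with the gap, 14 without the 8 libraries and 10 of 11 without LCO 10 mg/L replicates 2 and 3. The 4 were ENSDART00000180809.1 and ENSDART00000185964.1 at 10 mg/L, at -0.40 and -0.30 without replicates 2 and 3 and at -0.11 and -0.35 without the 8 libraries, both settings leaving out the libraries that carried the rise. The gene list tests and the fit on protein coding genes could not be run. Simulated 1.5-fold changes were recovered in 49.3% of 67 transcripts above a minimum mean CPM for LCO 10 mg/L vs control. What sets that share was not tested, and thinning to equal totals gave 2244 calls against 2470.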

Other observations

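Some transcripts set all exposed libraries apart from the controls, a count made after seeing the data. In 80 transcripts all 15 exposed libraries lay above all 5 controls, and in 335 all 15 lay below. Of 100 random sets of 5 of the 20 libraries taken as the controls, 0 gave as many in either direction, and the highest counts were 21 and 76. The third rise under ion, ENSDART00000055287.6, was chosen after its values were seen. It was at 15.1 ± 2.77 CPM in controls, 22.3 ± 3.84 at 1 mg/L, 28.4 ± 8.16 at 10 mg/L and 37.1 ± 12.8 under ion (SD, n = 5), and edgeR called it at 10 mg/L (adjusted p = 0.0209) and under ion (adjusted p = 0.0416) but not at 1 mg/L (adjusted p = 0.108).

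Over all 39355 transcripts, the fold changes at 10 mg/L had the same sign as those under ion in 73.6% and as those at 1 mg/L in 78.1%. Unchanged groups simulated against the same controls gave 66.3% and 66.2%, and with disjoint controls the observed shares were 63.4% and 68.4%.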
